A study of Mus musculus with 14 samples.

How the data were processed

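RNA of 14 mouse thymic lymphomas was measured on exon arrays, 7 tumours of the Vav-SB model and 7 of the CD4-SB model of T-cell acute lymphoblastic leukaemia (T-ALL). In both models Sleeping Beauty transposons jump in the genome and mutate genes where they insert. Per the labels' protocols, frozen tumours gave total RNA, which was amplified into cDNA by a single-primer isothermal method starting from a small input, then fragmented and labelled with biotin. Amplification from little RNA adds spread between arrays and can treat parts of a transcript unequally.

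The deposited table holds log2 values per probe set, a group of probes that mostly covers 1 exon, and 1 column per tumour. RMA and Partek are named in the submitters' processing notes, without versions. RMA in general subtracts background, aligns the arrays' distributions and summarises probes. The background step, the filter on probe sets and the log base are not given in the sources used here; the range of the values, 2.03 to 14.03, lies in the range of log2 RMA values, and values are read as log2 throughout. Column medians lie between 7.46 and 7.50, so a change in the total RNA of a tumour cannot be seen. Correlations of all probe sets between 2 tumours ran from 0.877 to 0.968, and 0 pairs were identical. The number of arrays, 7 per model, limits the precision, and low values lie near background, where folds are understated.

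Of 194293 probe sets, 179496 had 1 gene symbol in the platform annotation, 1328 had several and 13469 had none there. Only those with 1 symbol named genes. Symbols were updated through a mouse gene table of assembly GRCm38.p6. Of the symbols, 13727 were current, 2014 were replaced by way of a synonym, 32 had several possible replacements, 25 were kept because the current symbol was in use, and 5 were unmatched. Positions of probe sets were not used here, so no coordinates are given and the order of probe sets along a gene is unknown. The mean over a gene's probe sets gave 15803 genes, with a median of 9 probe sets and at most 115 per gene. No filter on dim genes was applied.

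Groups came from the strain label, and replicates were numbered in accession order within a model. The first number of the tumour titles is shared by some CD4-SB tumours, so that 7 CD4-SB tumours carry 4 numbers and 7 Vav-SB tumours carry 7. CD4-SB replicates 1 and 2 share 1 number and replicates 5, 6 and 7 another. Where 1 tumour per title number was kept, CD4-SB replicates 1, 3, 4 and 5 stayed. The labels do not say what this first number means or that each tumour came from a separate animal, so p-values measure the spread between these tumours.

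Differences are Vav-SB minus CD4-SB. Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and every adjusted p of a gene comes from that fit unless said otherwise. Intervals are at the 95% level. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and fry beside it, adjusted over 23 lists. The lists, with the sex-linked list 387 entries of which 333 were measured, were written before the data were examined, from textbook knowledge. A list of sex-linked genes served only to check the animals. Similarity of tumours was tested by an exact permutation test over 3432 splits. Probe sets that differ from the rest of their gene were tested with limma's diffSplice on 14165 genes with at least 3 probe sets (177027 probe sets).

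The genes named follow a rule fixed at the same time. It takes the 12 largest folds in each direction past the threshold whose higher mean lies above the median of all genes, up to 4 members past the threshold per list, and 20 genes of prior interest, of which 18 were measured. It also takes the 8 smallest adjusted p of the probe set test with Notch1 and Ikzf1, and insertion targets with a tumour apart from the rest of its model by Dixon's test. Genes named outside this rule are marked as chosen after their values were seen, or are further members of a list.

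The gene test, camera at the preset correlation and the probe set test were checked on simulated data. These were drawn from the means and spreads of the real genes or probe sets. Camera at an estimated correlation and fry were not checked in this way. The similarity test was only run on random values in 200 rows with no difference planted (exact permutation p = 0.145, one-sided). For the gene test, with 200 of 15803 genes changed, 40% of genes changed by 0.5 on the log2 scale were recovered, 82% of those changed by 1, and 100% of those changed by 2 or 4, with 7 calls among unchanged genes. A list shifted by 1 on the log2 scale was recovered, with 0 other lists called. Simulated genes varied independently of one another, so this does not show how often lists of correlated genes are called without a difference. For the probe set test on 14165 genes, 100% of 200 genes in which some probe sets were changed by 2 on the log2 scale were recovered, but 83 unchanged genes were called as well. That test uses 1 spread per gene. A form with a spread per probe set (limma on probe sets minus their gene's mean, then Simes' test per gene), added after that check, recovered 98% with 6 calls among unchanged genes, and its values are given beside the main ones.

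Alternatives were quantile normalization, centring, dim genes or probe sets left out, a median over probe sets, a trended and robust prior, the title number as a random block, 1 tumour per title number, array weights, a covariate of Y-linked genes, an estimated correlation, Simes' test, the 1000 most variable genes, and leaving out each tumour. The planned sex covariate was to include an X-linked transcript that was not analysed here, so only Y-linked genes entered it. Added after seeing the data were a covariate of other cell types' markers, the probe set test on genes changed by under 1.2-fold, and the spread per probe set. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.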

Results

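Exon array values of 14 thymic lymphomas were compared between the Vav-SB and the CD4-SB model, with 7 tumours each. According to the series title, the question is how the cell of origin influences which mutations are selected in mouse T-ALL. The arrays covered 15803 named genes, whose median level was 7.22 on the log2 scale. Levels below are means of log2 values ± SD with n = 7 tumours per model.

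Genes of immature thymocytes stood far higher in Vav-SB tumours. Dntt, which encodes the terminal transferase that adds nucleotides to rearranging antigen receptor genes, was at 11.25 ± 0.61 in Vav-SB and 5.47 ± 0.43 in CD4-SB, a 54.9-fold difference (adjusted p = 3.28e-09). Rag1, a subunit of the recombinase that cuts those genes, was 21.6-fold higher (10.52 ± 0.51 against 6.09 ± 0.86, adjusted p = 1.65e-06), and its partner Rag2 was 10.4-fold higher (8.39 ± 0.83 against 5.00 ± 1.56, adjusted p = 0.00225). Notch1, the receptor that drives T-lineage commitment and is a T-ALL oncogene, was 9.03-fold higher, at 10.67 ± 0.42 against 7.5 ± 0.23 (adjusted p = 2.9e-08), with every Vav-SB tumour above every CD4-SB tumour.

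The other large differences toward Vav-SB were Arpp21 at 30.5-fold, Endou (an endoribonuclease) at 28.2-fold, Trat1 (an adaptor of the T-cell receptor) at 10.6-fold, and Lig4 (the ligase of DNA end joining) at 10.3-fold. Sva followed at 9.89-fold, Aqp11 (an aquaporin) at 9.36-fold, H2-T3 (a nonclassical MHC class I gene) at 9.16-fold and Iltifb (a copy of the interleukin-22 gene) at 9.01-fold. Their adjusted p ran from 3.18e-12 for Arpp21 and Endou to 0.0193 for Iltifb. Rag2, Trat1 and Iltifb overlapped between the models: Rag2 was at 8.49 in 1 CD4-SB tumour, Trat1 at 4.89 in 1 Vav-SB tumour and Iltifb at 5.89 in another. The calls of Trat1 and Iltifb were lost with the level of other cell types' markers as a covariate (adjusted p = 0.104 and 0.0777), and that of Iltifb with array weights (adjusted p = 0.0666). With the covariate the log2 difference of Trat1 went from 3.40 to 3.08 and that of Iltifb from 3.17 to 3.89. Their standard errors grew from 0.71 to 1.01 and from 0.82 to 1.15. H2-T3 and Iltifb belong to families of near-identical genes, so their probe sets can bind relatives.

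Crtam, a surface receptor of activated T and NK cells, was 7.53-fold higher in CD4-SB (8.81 ± 0.47 against 5.90 ± 0.27, adjusted p = 3.31e-07). S100a10, a partner of annexin A2, was 6.07-fold higher (11.39 ± 0.30 against 8.79 ± 0.71, adjusted p = 2.94e-05). In both genes every CD4-SB tumour lay above every Vav-SB tumour. The immunoglobulin genes Ighg2b, Igkc and Ighg1, transcripts of antibody-forming B-lineage cells, were 9.89-fold, 6.99-fold and 5.97-fold higher (adjusted p = 0.00398, 0.00276 and 0.0292). Immunoglobulin probe sets and those of Gvin1 can bind relatives of their gene. The remaining large differences were Saa3 (an acute-phase protein) at 7.76-fold, Gvin1 at 7.57-fold, Ddc (a decarboxylase of amine synthesis) at 6.39-fold, Akr1c13 at 6.32-fold and Cxcl13 (a B-cell chemokine) at 5.86-fold. Il23r, the interleukin-23 receptor, was 8.05-fold higher and Clnk, a signalling adaptor, 6.27-fold higher on average. Their spread in CD4-SB was wide, at 8.78 ± 2.74 and 8.58 ± 2.22. The calls of Il23r, Saa3, Clnk and Ighg1 were lost without 11, 7, 9 and 8 of the tumours left out singly, with adjusted p up to 0.0952, 0.0555, 0.0633 and 0.0609. With 1 tumour per title number the calls of Il23r, Saa3, Clnk and Cxcl13 were lost (adjusted p = 0.0717, 0.184, 0.0508 and 0.0591). The level of Y-linked genes as a covariate ended those of Il23r, Saa3 and Clnk (adjusted p = 0.104, 0.0635 and 0.0686), and a median over probe sets that of Il23r (adjusted p = 0.0644). With the level of other cell types' markers as a covariate the log2 difference of Ighg2b went from -3.31 to -1.57, Igkc from -2.80 to -1.50, Ighg1 from -2.58 to -0.81, Gvin1 from -2.92 to -1.11 and Cxcl13 from -2.55 to -1.22. These 5 calls ended there (adjusted p = 0.19, 0.144, 0.607, 0.42 and 0.374), as did those of Saa3, Akr1c13, Il23r and Clnk (adjusted p = 0.19, 0.1, 0.416 and 0.351). The Saa3 difference stayed close, from -2.96 to -2.93, while its standard error grew. Akr1c13 went from -2.66 to -2.04, Il23r from -3.01 to -2.04 and Clnk from -2.65 to -1.84, also with larger standard errors.

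**Figure D1:**
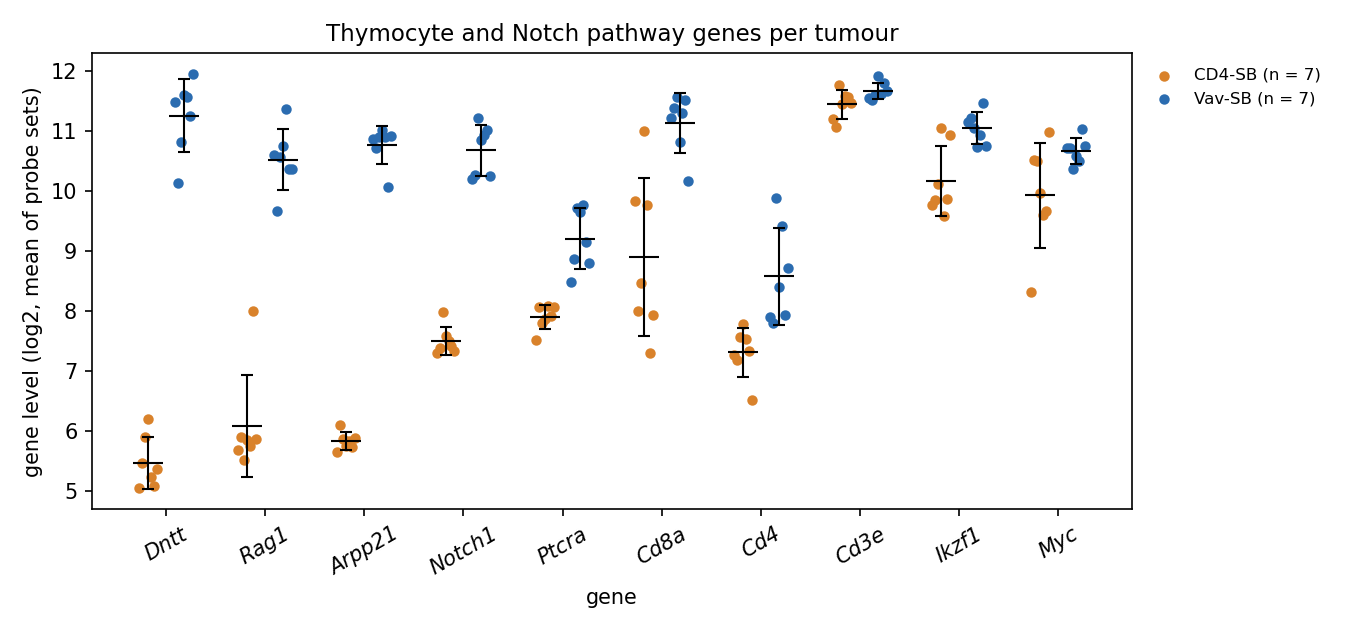
Gene levels on the log2 scale (y axis) of 10 genes (x axis), with 1 point per tumour, CD4-SB on the left and Vav-SB on the right of each gene, and bars giving the mean and SD (n = 7). Dntt, Rag1, Arpp21, Notch1 and Ptcra of all Vav-SB tumours lie above those of all CD4-SB tumours, while Cd3e, at 11.66 against 11.44, and Myc overlap.

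In all, 2284 of 15803 genes passed the threshold, 1150 higher in Vav-SB and 1134 higher in CD4-SB. At least 2-fold differences numbered 239 and 297, and at least 4-fold differences 43 and 30. The 7 and 7 tumours did not overlap in 638 genes, or 4.04% of genes, where chance gives 0.0583%. The calls of 51 of the 83 named genes past the threshold ended without a change of sign, that of H2-Aa ended with one, and 625 genes passed, with the mean level of 55 markers of myeloid, dendritic, B and stromal cells as a covariate, an alternative chosen after seeing the data. Of the 625, 410 were higher in Vav-SB and 215 in CD4-SB. In 26 of the 51 the difference stayed at or above the former one divided by 1.5, and in 25 it fell below that, while the standard error grew in 41. Trat1 went from 3.40 ± 0.71 (SE) to 3.08 ± 1.01 on the log2 scale, and Perp from -0.95 ± 0.26 to -0.96 ± 0.37, differences that stayed close while their errors grew and fewer genes passed in all. Spi1, which is not among the markers, went from -0.60 ± 0.18 to -0.01 ± 0.11, where the difference itself was lost. Itgax went from -1.31 ± 0.41 to -0.02 ± 0.31, but it is 1 of the 55 markers, so its loss is partly built in. Of the ended calls, those of H2-Aa, Irf8, Bst2, Cd37, C1qa, Fcgr3, Csf1r, Cd14, Dcn, Sparc and Pecam1 are of markers too. That marker level was 8.24 ± 0.43 in CD4-SB and 7.61 ± 0.24 in Vav-SB (exact permutation p = 0.00816, two-sided).

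All 15 measured genes typical of double-positive thymocytes, the stage that carries both CD4 and CD8, were higher in Vav-SB. Their mean level was 10.31 ± 0.18 in Vav-SB and 7.62 ± 0.42 in CD4-SB. Besides Dntt, Arpp21, Rag1 and Rag2, they included Cd8a (4.71-fold, adjusted p = 0.00729), Cd8b1 (5.79-fold, adjusted p = 0.000723) and Cd4 itself (2.41-fold, adjusted p = 0.0144), and 12 of the 15 passed with the other cell types' markers as a covariate. The Cd4 call was lost with 1 tumour per title number, at an adjusted p of 0.089. Of 13 genes of the earlier commitment stages, 10 rose in Vav-SB and 0 fell, among them Lef1 (5.11-fold, adjusted p = 0.000591), Tcf7 (3.4-fold, adjusted p = 0.0275), Tcf12 (3.05-fold, adjusted p = 6.57e-07), Gata3 (1.73-fold, adjusted p = 0.00843) and Bcl11b (1.61-fold, adjusted p = 4.5e-05). These are transcription factors of the T lineage. The Tcf7 call was lost with a median over probe sets, Y-linked genes as a covariate and other cell types' markers as a covariate (adjusted p = 0.0575, 0.0589 and 0.29), and without 3 of the tumours left out singly (up to 0.0555). That of Gata3 was lost with the marker covariate (adjusted p = 0.121), where its log2 difference went from 0.79 to 0.73 and its standard error from 0.18 to 0.25. There the Tcf7 difference went from 1.76 to 1.38. Il2ra, at 10.28 ± 2.01 against 8.23 ± 1.81, did not pass (adjusted p = 0.162), except without Vav-SB replicate 1 (adjusted p = 0.0474). Both lists passed with camera (adjusted p = 5.08e-20 and 2.52e-13) and with an estimated correlation (adjusted p = 0.00323 and 0.0216).

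Of 13 Notch targets, 7 rose and 1, Hey1, fell. Besides Notch1 itself, Dtx1 was 2.91-fold higher in Vav-SB (adjusted p = 0.000362), Ptcra, the pre-T-cell receptor alpha chain, 2.47-fold (adjusted p = 0.000604) and Notch3 2.45-fold (adjusted p = 0.000181). Adjusted over the list alone, 8 rose and 1 fell. The list passed with camera (adjusted p = 8.13e-06) but not with an estimated correlation (adjusted p = 0.0684). Of 15 genes of T-cell receptor signalling, 4 rose and 1 fell (6 and 1 adjusted over the list alone). The CD3 genes, which all T-lineage cells express, were close in both models: Cd3d was at 12.12 ± 0.24 in Vav-SB and 11.84 ± 0.21 in CD4-SB (adjusted p = 0.152), Cd3e at 11.66 ± 0.14 and 11.44 ± 0.24 (adjusted p = 0.196) and Cd247 at 9.0 ± 0.10 and 8.46 ± 0.50 (adjusted p = 0.0581), while Cd3g rose 1.31-fold (adjusted p = 0.00771). Ptprc, encoding CD45, was 1.93-fold higher, Plcg1 1.7-fold and Lat 1.47-fold, and Nfatc2 was 2.51-fold higher in CD4-SB, with adjusted p of 0.00394, 0.00829, 0.0122 and 0.00399. The marker covariate ended these 4 calls at differences of 0.99, 0.68, 0.59 and -0.94 (adjusted p = 0.0522, 0.132, 0.0966 and 0.144), and a median over probe sets that of Lat (adjusted p = 0.0704). The call of this list (adjusted p = 0.0117) was lost with an estimated correlation (adjusted p = 0.314) and with genes above the median level only (adjusted p = 0.0616). Lists share members, Notch1 being in 3 of them, and so are not independent.

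Of 24 measured genes that insertions are known to hit in mouse T-cell tumours, 6 rose and 2 fell (7 and 2 adjusted over the list alone). Myb was 4.08-fold higher in Vav-SB (adjusted p = 0.00119), Ikzf1 1.83-fold (11.04 ± 0.26 against 10.16 ± 0.59, adjusted p = 0.0182) and Runx1 1.61-fold (adjusted p = 0.0358), while Zeb2 was 1.77-fold and Runx3 1.58-fold higher in CD4-SB (adjusted p = 0.0267 and 0.00725). The Ikzf1 call was lost with a median over probe sets (adjusted p = 0.0666). With the other cell types' markers as a covariate the calls of Ikzf1, Runx1, Zeb2 and Runx3 ended at differences of 0.64, 0.96, -0.17 and -0.61 (adjusted p = 0.271, 0.0684, 0.682 and 0.108). The Runx1 call was also lost with 1 tumour per title number, a median over probe sets and Y-linked genes as a covariate (adjusted p = 0.105, 0.149 and 0.0523) and without 8 of the tumours left out singly (adjusted p up to 0.0729), and the Zeb2 call with Y-linked genes as a covariate (0.0558) and without 2 (up to 0.0578). Zmiz1 averaged 8.95 ± 0.25 in Vav-SB and 8.91 ± 0.88 in CD4-SB (adjusted p = 0.953). Myc was at 10.66 ± 0.21 and 9.93 ± 0.87 (adjusted p = 0.135), Mycn at 6.22 ± 0.51 and 6.72 ± 0.67 (adjusted p = 0.285), Stat5b at 9.37 ± 0.62 and 9.04 ± 1.24 (adjusted p = 0.716), and Pik3r5 at 8.60 ± 0.16 and 7.98 ± 0.60 (adjusted p = 0.071). Myc and Pik3r5 passed with 1 tumour per title number (adjusted p = 0.0436 and 0.00265) and without CD4-SB replicate 7 (0.0464 and 0.000411), and Pik3r5 with array weights (0.0376). Erg averaged 8.20 ± 1.64 in Vav-SB, where 3 tumours lay between 9.73 and 10.18 and the other 4 at or below 7.38, and 6.96 ± 0.33 in CD4-SB (adjusted p = 0.173). The list passed with camera (adjusted p = 0.00565), and with an estimated correlation the adjusted p was 0.0684.

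Among 16 transcription factor oncogenes of T-ALL, only Myb passed. Lmo2 was at 7.82 ± 0.47 in Vav-SB and 8.13 ± 0.22 in CD4-SB, Hoxa9 at 6.32 ± 0.16 and 6.22 ± 0.12, and the list did not pass (adjusted p = 0.488). Without Vav-SB replicate 3 Lmo2 passed at -0.47 (adjusted p = 0.0273). Of 22 early progenitor genes, 1 (Sox4, 2.05-fold, adjusted p = 0.000286) rose and 4 fell, Meis1 (2.15-fold, adjusted p = 0.00295), Cd44 (2.05-fold, adjusted p = 0.0238), Spi1 (1.51-fold, adjusted p = 0.0342) and Cebpa, and 1 and 7 did so adjusted over the list alone. The list passed at an adjusted p of 0.035, which was lost with an estimated correlation (adjusted p = 0.499), and with the marker covariate its direction turned (adjusted p = 0.593). Other settings that ended it were quantile normalization (adjusted p = 0.0533), genes above the median level (0.394), a median over probe sets (0.0617), bright probe sets (0.235), a trended prior (0.0809) and the title number as a random block (0.0768). It was also lost without 7 of the tumours left out singly (adjusted p up to 0.0828), and so were the calls of Spi1 without 9 (up to 0.0704) and Cd44 without 1, Vav-SB replicate 4 (0.051). With the marker covariate Meis1 went from -1.10 to -0.82, Cd44 from -1.03 to -0.54 and Spi1 from -0.60 to -0.01, and all 3 calls ended (adjusted p = 0.113, 0.418 and 0.968). Y-linked genes as a covariate ended those of Cd44 and Spi1 (adjusted p = 0.0549 and 0.0653), and a median over probe sets that of Spi1 (adjusted p = 0.062). Kit (6.80 ± 0.62 against 7.06 ± 0.69) and Il7r (8.36 ± 1.16 against 8.0 ± 0.87) did not pass, with adjusted p of 0.666 and 0.703.

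Of 17 PI3K-Akt genes 4 rose and 3 fell (5 and 3 adjusted over the list alone). Rictor, a part of mTOR complex 2, was 1.52-fold higher in Vav-SB (adjusted p = 0.0109). The phosphatase gene Inpp5d was 2.06-fold and the kinase genes Pik3cb and Pik3cd 1.92-fold and 1.55-fold higher in CD4-SB (adjusted p = 0.000537, 0.0033 and 0.0264). Of 13 p53 targets 1 rose, Trp53inp1 (2.58-fold, adjusted p = 0.00673), and 3 fell, Cdkn1a (2.15-fold, adjusted p = 0.00709), Perp (1.93-fold, adjusted p = 0.0244) and Ccng1 (1.43-fold, adjusted p = 0.0121). The calls of Pik3cd and Perp were lost without 3 and 2 of the tumours left out singly (adjusted p up to 0.0547 and 0.0539). With 1 tumour per title number those of Rictor, Perp and Ccng1 were lost (adjusted p = 0.0555, 0.0658 and 0.0734). A median over probe sets took Ccng1 from -0.51 to -0.26 and Perp from -0.95 to -0.58 (adjusted p = 0.198 and 0.063), and Y-linked genes as a covariate ended the Perp call (adjusted p = 0.0569). Of 15 cytokine receptor and JAK-STAT genes 0 rose and 2 fell, Il4ra (1.73-fold, adjusted p = 0.00278) and Jak3 (1.38-fold, adjusted p = 0.00272). Of 15 mature T-cell genes 0 rose and 2 fell, the MHC class I gene H2-K1 (3.58-fold, adjusted p = 0.00391) and Runx3. With the marker covariate Pik3cb went from -0.94 to -0.39, Pik3cd from -0.64 to -0.46, Cdkn1a from -1.10 to -0.71, Il4ra from -0.79 to -0.46 and H2-K1 from -1.84 to -0.94 (adjusted p = 0.143, 0.318, 0.215, 0.138 and 0.185). The calls of Rictor, Perp and Jak3 ended there at 0.70, -0.96 and -0.40 (adjusted p = 0.0655, 0.17 and 0.0777). Of 15 Myc target and ribosome biogenesis genes 0 passed in limma, and 1 had an unadjusted p under 0.05. The PI3K-Akt, p53, JAK-STAT, mature T-cell and Myc target lists did not pass, with adjusted p of 0.271, 0.32, 0.0698, 0.377 and 0.762. The JAK-STAT list, lower in Vav-SB, passed with 1 tumour per title number (adjusted p = 0.016), array weights (0.0386) and Y-linked genes as a covariate (0.0272), and without 4 of the tumours left out singly (down to 0.0195). The marker covariate turned the direction of the JAK-STAT and mature T-cell lists (adjusted p = 0.531 and 0.216), and with it the PI3K-Akt and Myc target lists passed (adjusted p = 0.0488 and 8.23e-06).

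Of 17 myeloid genes 0 rose and 7 fell in Vav-SB (9 adjusted over the list alone). C1qa, a complement gene of macrophages, was 2.81-fold higher in CD4-SB (9.83 ± 0.58 against 8.34 ± 0.58, adjusted p = 0.00334), Fcgr3, an Fc receptor, 2.44-fold (adjusted p = 0.0018), Csf1r 2.17-fold (adjusted p = 0.0103) and Tyrobp, at 11.74 against 10.67, 2.1-fold (adjusted p = 0.00143). Of 13 dendritic cell and MHC class II genes 0 rose and 4 fell (9 adjusted over the list alone), H2-Aa (2.53-fold, adjusted p = 0.0467), Itgax (2.47-fold, adjusted p = 0.0437), Irf8 (1.66-fold, adjusted p = 0.0135) and Bst2 (1.48-fold, adjusted p = 0.0419). Of 11 B-cell genes 0 rose and only Cd37 fell (1.91-fold, adjusted p = 0.00337), while adjusted over the list alone 5 fell. These 3 lists passed with camera (adjusted p = 9.76e-06, 3.21e-05 and 0.00219) and were lost with an estimated correlation (adjusted p = 0.178, 0.364 and 0.499). The calls of H2-Aa, Itgax and Bst2 were each lost without 11 of the tumours left out singly, and that of Cd14, 2.12-fold higher in CD4-SB, without 7 (adjusted p up to 0.0963, 0.0878, 0.0876 and 0.0664). Y-linked genes as a covariate ended these 4 calls too (adjusted p = 0.0846, 0.0822, 0.0612 and 0.0518). Quantile normalization ended those of H2-Aa and Itgax (0.0504 and 0.0517), arrays centred on their median those of H2-Aa and Bst2 (0.0503 and 0.0543), array weights that of Bst2 (0.0525) and a median over probe sets that of Itgax (0.0567). The marker covariate, which is made of such genes, ended the myeloid call (adjusted p = 0.229) and turned the dendritic cell and B-cell lists (adjusted p = 0.994 and 0.593). It also ended the calls of C1qa, Fcgr3, Csf1r, Irf8 and Cd37 (adjusted p = 0.157, 0.0995, 0.408, 0.439 and 0.15).

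Of 14 stromal and endothelial genes 2 rose, Fbln1 (2.31-fold, adjusted p = 0.000154) and Pecam1 (1.86-fold, adjusted p = 0.00312), and 2 fell, Dcn (2.94-fold, adjusted p = 0.0326) and Sparc (2.14-fold, 11.35 ± 0.57 in CD4-SB, adjusted p = 0.0193). Adjusted over the list alone, 2 rose and 5 fell. Of 11 thymic epithelial genes only the keratin gene Krt5 fell (2.03-fold, adjusted p = 0.0114). Neither list passed (adjusted p = 0.173 and 0.69), except the stromal list with 1 tumour per title number (adjusted p = 0.0354). The Dcn call was lost with Y-linked genes as a covariate (adjusted p = 0.0505) and without 7 of the tumours left out singly (up to 0.0725). With the marker covariate the calls of Pecam1, Dcn, Sparc and Krt5 ended at 0.86, -0.13, -0.72 and -0.85 (adjusted p = 0.0636, 0.869, 0.318 and 0.179), and the stromal list turned (adjusted p = 0.229). Of 9 erythroid genes 0 passed in limma and 2 had an unadjusted p under 0.05. Their list was higher in Vav-SB (adjusted p = 0.0333), which was lost with an estimated correlation (adjusted p = 0.499) and without 3 of the tumours left out singly (adjusted p up to 0.13). It was also lost with 1 tumour per title number (adjusted p = 0.0963), the title number as a random block (0.0768), array weights (0.086), a trended prior (0.0809), genes above the median level (0.353) and bright probe sets (0.222).

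Of 14 NK, NKT and cytotoxic genes 1 rose, Sox13 (1.48-fold, adjusted p = 0.00269), and 1 fell, Fcer1g, a receptor subunit that myeloid cells also express (2.74-fold, adjusted p = 0.00146). Adjusted over the list alone, 1 rose and 3 fell. Of 6 measured gamma-delta T-cell genes 3 rose, Il17rb (6.08-fold, adjusted p = 0.00218), Cd163l1 (3.73-fold, adjusted p = 0.0161) and Sox13, and Il23r fell. With the other cell types' markers as a covariate these 4 calls ended, at 2.10, 1.27, 0.43 and -2.04 (adjusted p = 0.0844, 0.291, 0.0959 and 0.416). That of Sox13 was also lost with a median over probe sets and with bright probe sets only (adjusted p = 0.137 and 0.125). Of 10 interferon response genes only Bst2 fell (5 adjusted over the list alone), and of 12 immediate early and stress genes only Jun, a subunit of AP-1, fell (1.96-fold, adjusted p = 0.00697). The cytotoxic, interferon and immediate early lists were lower in Vav-SB (adjusted p = 0.0222, 0.0117 and 0.0267). Each call was lost with an estimated correlation (adjusted p = 0.499, 0.499 and 0.48) and without CD4-SB replicate 3 (adjusted p = 0.0684, 0.0808 and 0.0877), and with genes above the median level only (adjusted p = 0.109, 0.113 and 0.107). Leaving out CD4-SB replicate 6 also ended the cytotoxic call. The cytotoxic and immediate early calls were lost with the title number as a random block (adjusted p = 0.0553 and 0.0768), bright probe sets (0.123 and 0.163) and the marker covariate (0.728 and 0.963), and the latter with a trended prior (0.0525). With that covariate the interferon list turned (adjusted p = 0.564), and Jun went from -0.97 to -0.35 (0.29), Fcer1g from -1.45 to -0.89 (0.0844) and Bst2 from -0.56 to -0.23 (0.578). The gamma-delta list did not pass (adjusted p = 0.329). Of 21 proliferation genes Tyms, the thymidylate synthase gene, rose (1.92-fold, adjusted p = 0.0478), and 0 passed adjusted over the list alone, where 6 had an unadjusted p under 0.05. The proliferation list was higher in Vav-SB (adjusted p = 0.00152), and with an estimated correlation the adjusted p was 0.525. Its mean level was 7.41 in CD4-SB replicate 3 and 8.80 to 9.91 in the other CD4-SB tumours. With the other cell types' markers as a covariate the list turned lower in Vav-SB (adjusted p = 0.593) and the Tyms difference went from 0.94 to 0.16 (adjusted p = 0.8). The Tyms call was also lost with a median over probe sets (adjusted p = 0.1), bright probe sets (0.0565) and a trended prior (0.05) and without 10 of the tumours left out singly (adjusted p up to 0.0936).

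In all 14 of 23 lists passed with camera, 7 higher and 7 lower in Vav-SB, and 2, the double-positive and the commitment list, held with an estimated correlation. Of 100 splits of the tumours into 7 and 7, 5 gave at least 14 lists, the real one included. The median over the other splits was 6 lists. Fry, which tests whether the genes of a list move on balance in 1 direction, gave 8 lists, and its mixed form, which tests for change in either direction, gave 19. Fry's 8 were the double-positive, commitment, Notch target, insertion target, T-cell receptor, myeloid, dendritic cell and immediate early lists (adjusted p from 5.21e-09 to 0.0455). The early progenitor, proliferation, interferon, cytotoxic, B-cell and erythroid lists passed with camera but not by fry (fry adjusted p from 0.0805 to 0.185). The gamma-delta list had a median difference of -0.35 and a mean of -0.09 while camera put it higher in Vav-SB. The thymic epithelial list had a median of 0.02 and a mean of -0.16, and the Myc target list 0.01 and -0.02, and camera put both lower. For lists with a single pair of counts above, the counts adjusted over the list alone were the same.

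**Figure D2:**
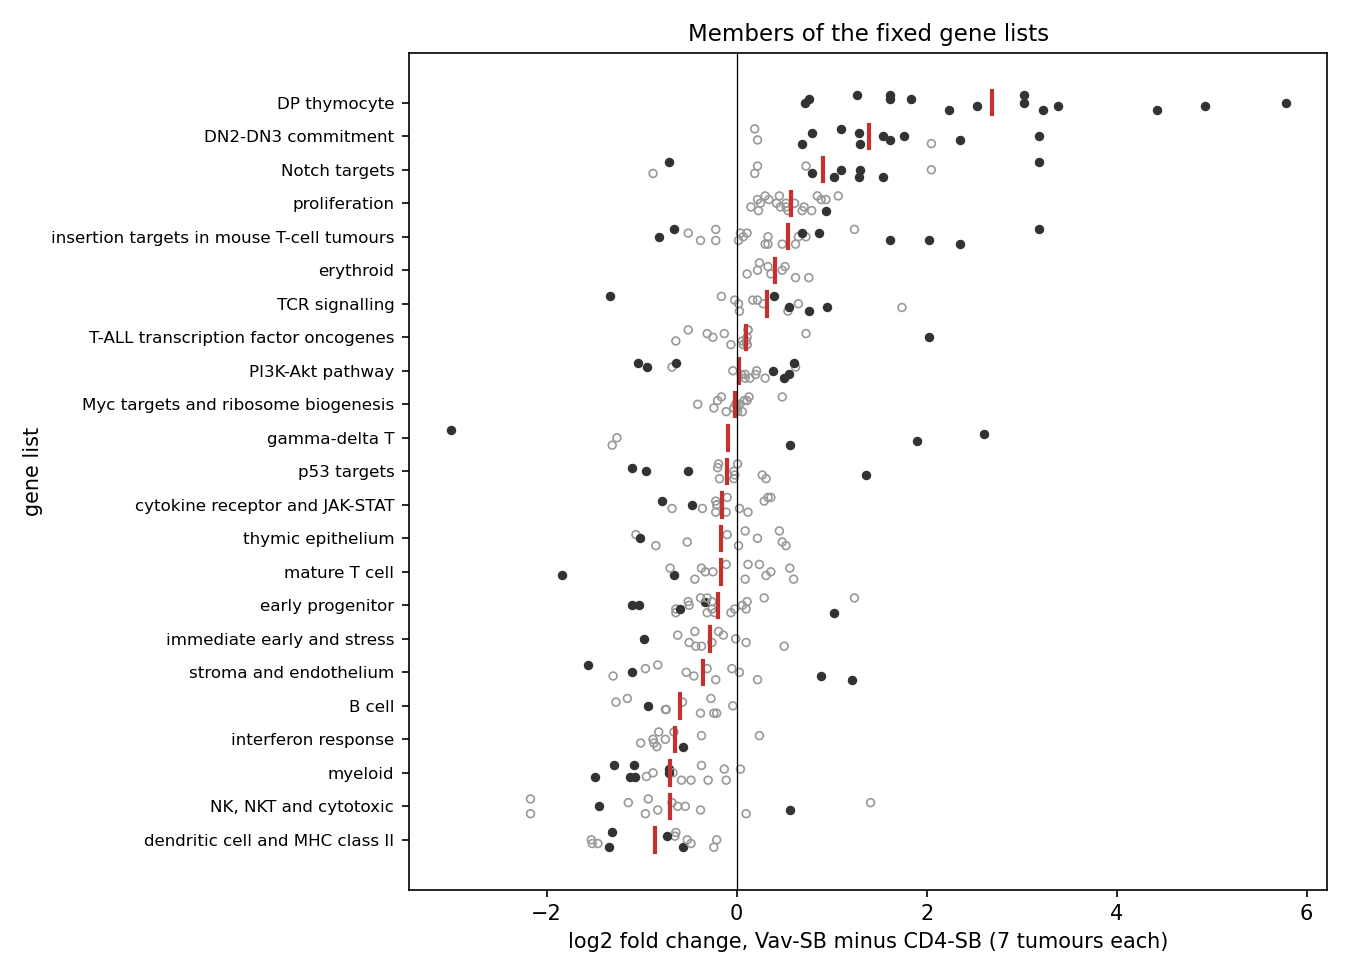
Log2 fold change, Vav-SB minus CD4-SB (x axis), of the measured members of 23 gene lists (y axis), with 1 point per gene, filled where the gene passed an adjusted p of 0.05, and a red bar at the mean of the list. All 15 double-positive thymocyte genes lie above 0, with a mean of 2.69, while the dendritic cell and MHC class II list has a mean of -0.86.

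**Figure D3:**
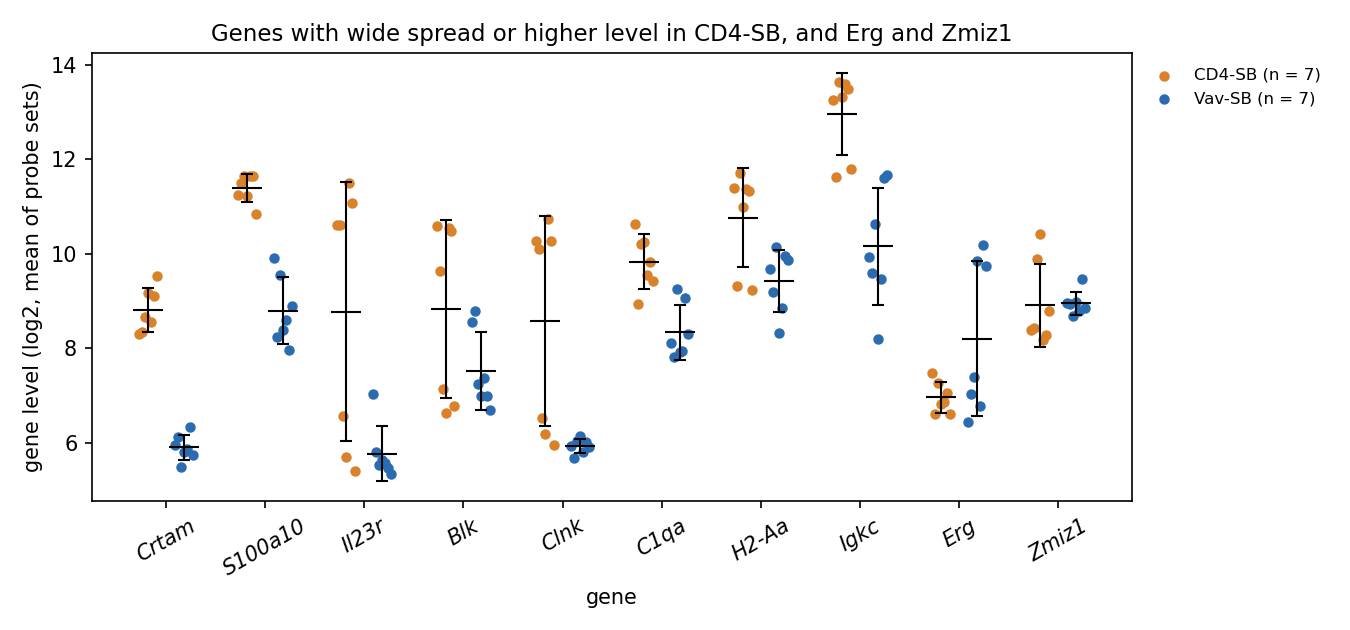
Gene levels on the log2 scale (y axis) of 10 genes (x axis), with 1 point per tumour, CD4-SB on the left and Vav-SB on the right of each gene, and bars giving the mean and SD (n = 7). Crtam and S100a10 of the models do not overlap, whereas Il23r and Clnk in CD4-SB and Erg in Vav-SB spread widely, with SDs of 2.74, 2.22 and 1.64.

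The model separated whole expression profiles. Correlations of gene profiles, each gene centred on its mean over all tumours, averaged 0.29 within Vav-SB, 0.11 within CD4-SB and -0.30 between the models. Within-model correlations exceeded those between models by 0.51 (exact permutation p = 0.000583, one-sided, over 3432 splits), the smallest p this comparison can give. The first principal component held 35.3% of the variance and the second 13.5%. CD4-SB tumours lay farther from one another, with a root mean square log2 distance to the other tumours of the model of 0.46 ± 0.05, against 0.32 ± 0.05 in Vav-SB (exact permutation p = 0.00175, two-sided, n = 7 each). The permutation shuffled the finished distances and did not recompute them. Distances within a model share tumours and are not independent, so this p is a rough guide only.

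Exon-level probe sets were then compared with the rest of their gene, since insertions can truncate a transcript or start one inside a gene. All but 1 of 39 Notch1 probe sets were over 2-fold higher in Vav-SB. Their differences ran from 0.20 to 4.76 on the log2 scale with a median of 3.45 (adjusted p = 1.74e-72). Ikzf1, whose 7 probe sets differed by 0.78 to 1.06, did not pass (adjusted p = 1). Arpp21 (25 probe sets, 2.10 to 8.05), Gfra1, a receptor of GDNF (13, 0.24 to 6.34), Notch3 (38, -0.06 to 3.08), Brdt, a bromodomain gene of the testis (19, -0.30 to 4.35), and Smo, the Hedgehog signal transducer (17, -0.14 to 2.73), also passed. Odz1 (35 probe sets, -0.68 to 3.87) and Acsbg1 (19, -4.84 to 0.53) passed although their genes differed by only 0.45 and -0.93. With a spread per probe set, chosen after the test on simulated data, these 8 genes also passed, with adjusted p from 6.95e-09 for Gfra1 to 0.000937 for Smo and 7.37e-07 for Notch1.

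Of 14165 genes tested, 1508 passed, of which 840 had also passed at the gene level. On simulated data this test called 83 unchanged genes, and with a spread per probe set, which called 6 there, 1026 genes passed, 744 of them shared. Among genes changed at least 2-fold, 235 of 641 passed (36.7%), against 477 of 9332 (5.11%) among genes changed under 1.2-fold.

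**Figure D4:**
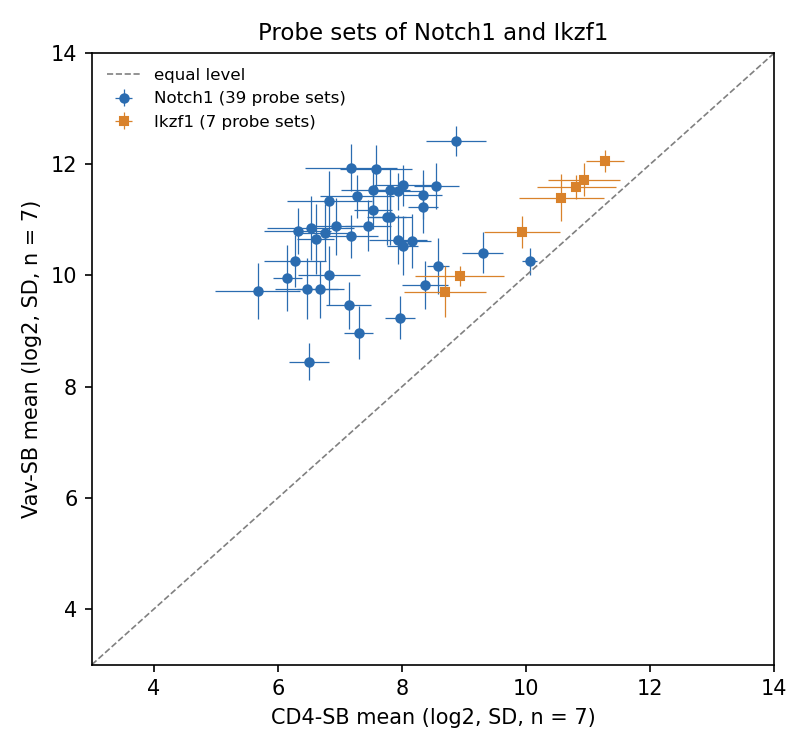
Mean level in Vav-SB (y axis) against mean level in CD4-SB (x axis), both on the log2 scale, of 39 Notch1 and 7 Ikzf1 probe sets, with 1 point per probe set, bars giving the SD (n = 7) and a dashed line at equal levels. All Notch1 probe sets lie above the line by 0.20 to 4.76, and those of Ikzf1 by 0.78 to 1.06.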

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

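The tests on CD3 genes, Y-linked genes, title numbers, shifts of other cell types and genes changed at least 2-fold were chosen after the results they bear on were seen, as were the marker covariate and the spread per probe set.

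In 22 genes a tumour stood far from the other 6 of its model, 23 times in 188 combinations of gene and model. Stat5b, Pik3r5 and Zeb2 had been named because a tumour stood apart. Without these 3 genes it was 20 times in 182 combinations, where chance gives about 1 in 20, or 9.1. In CD4-SB replicate 6, Rag1 was at 8.0 and Rag2 at 8.49, with the next tumours at 5.91 and 4.82, and Dtx1 was at 7.96. In CD4-SB replicate 7, Il17rb was at 9.64 (next 6.71), Endou at 7.20, Pik3r5 at 9.25 and Lmo2, the lowest, at 7.67. Single CD4-SB tumours also stood apart in Notch1 (7.98 in replicate 3, next 7.58), Cxcl13 (8.02 in replicate 4, next 10.01), Lig4 (6.27 in replicate 2) and Zeb2 (10.08 in replicate 1). In Vav-SB replicate 3, Trat1 was at 4.89 (next 8.70), Cdkn1a at 8.15, Stat5b at 10.66 and Tyms at 8.32. In Vav-SB replicate 2, Gata3 was at 10.54, Sox4 at 8.50 and Tcf7 at 12. Other Vav-SB tumours stood apart in Arpp21 (10.07) and Zmiz1 (9.46) in replicate 6, Kit (8.14, next 6.84) and Rag2 (6.64) in replicate 7, and Il23r (7.03) in replicate 1.

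The first pattern is the higher level of thymocyte and Notch genes in Vav-SB. Fewer T-lineage cells in the CD4-SB tumours would lower the CD3 genes alike, but the highest upper 95% bound of their shifts was 0.93. Their mean shift was 0.36, against 2.69 for the double-positive list (exact permutation p of the difference = 0.000583, two-sided, the smallest it can give), which argues against fewer such cells for that list. The Notch target list shifted by a mean of 0.91, within that bound, so the comparison cannot decide for Notch targets. For the double-positive genes sex and shared title numbers are argued against as well, since 14 of 15 stayed past the threshold with the level of Y-linked genes as a covariate and 13 of 15 with 1 tumour per title number. Notch targets were not counted in these checks, but their list kept its camera call in both settings. What stays open, untested, is the model itself: the tumours may have been arrested at different stages of thymocyte development.

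The second pattern is the higher level of other cell types' markers in CD4-SB. With 1 tumour per title number (CD4-SB replicates 1, 3, 4 and 5) the myeloid and dendritic cell lists passed at the preset correlation. The larger adjusted p was 3.04e-06, and the lists shifted by -0.93 and -1.23 (exact permutation p = 0.00606 and 0.00303, two-sided, n = 7 and 4). With all tumours the shifts were -0.70 and -0.86, and neither list passed with an estimated correlation (adjusted p = 0.178 and 0.364). The omitted CD4-SB replicates 2, 6 and 7 had myeloid levels of 8.33, 8.63 and 8.41, against a Vav-SB mean of 8.06. Their dendritic levels were 7.66, 9.20 and 7.62, against 7.79. Other choices of tumour were not tried, so this check cannot exclude shared title numbers. A lower share of tumour T cells would raise all other types alike. Markers whose CD4-SB mean lay above the median of all genes shifted by -0.69 for B cells, -0.78 for myeloid and -0.98 for dendritic genes. Thymic epithelial genes shifted by -0.28 and stromal genes by -0.57 (exact permutation p = 0.0134, 0.00641, 0.0192, 0.299 and 0.0122 in this order, two-sided). That filter used the CD4-SB level alone and so leans toward shifts in this direction. Over all measured members the mean shifts were -0.60, -0.70, -0.86, -0.16 and -0.35 (exact permutation p = 0.028, 0.00641, 0.0186, 0.494 and 0.0618, two-sided). The smallest adjusted exact permutation p between any pair of the filtered lists was 0.493. A lower share of tumour cells and a change in particular cell types therefore cannot be told apart with 7 tumours each. The dim erythroid list was left out of these pairs because too few of its members passed the filter. It was at 6.79 in Vav-SB and 6.39 in CD4-SB (exact permutation p = 0.0519, two-sided). That list and the stromal genes Fbln1 and Pecam1 went the other way, which excludes neither explanation. A difference between the models in the cells that accompany a tumour, or in what the tumour cells themselves express, may also account for it and was not tested.

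The third pattern is the set of genes whose probe sets differ from the rest of the gene. Of genes changed at least 2-fold 36.7% passed, against 5.11% of genes changed under 1.2-fold, as probe sets that answer less to the same change would give. Any unequal change among probe sets is easier to see in a gene that changes more. This share therefore cannot tell that explanation from others. Among the latter, 209 genes that passed held a probe set changed over 2-fold, or 2.24%, which met both the bound written for that explanation and the bound written against it, so the 2 cannot be told apart there. Probe sets of Adam28 (1.51 and -1.11), Per3 (2.07 and -1.46) and Rabgap1l (2.37 and -1.21), named after their values were seen, moved in opposite directions. Of their 30, 24 and 26 probe sets, 1, 1 and 2 were called higher and 1, 3 and 1 lower. A weak probe set would not turn a direction, which argues against that explanation for these few probe sets only. The other splits held at most 1 such gene. They had a median of 0 genes past the threshold, so that comparison bears little on weak probe sets. Insertions, splicing and probes that bind other transcripts stay open, untested.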

How the results depend on the processing

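The marker covariate, the restriction to genes changed under 1.2-fold and the spread per probe set were chosen after seeing the data. Counts of genes past the threshold ran from 1766 (median over probe sets) to 2993 (array weights) in the alternatives written down beforehand, and were 625 with the marker covariate, 503 of them shared. That covariate differs between the models and so takes part of the model's difference with it. Lists past the threshold numbered 8 with genes above the median level only, 8 with the marker covariate and 2 with an estimated correlation, and 10 to 15 otherwise. Genes whose probe sets differ numbered 899 of 9351 with bright probe sets only (723 shared), where fewer genes are tested. They numbered 324 of 9283 among genes changed by under 1.2-fold that had not passed at the gene level, tested and adjusted alone. The similarity of tumours ran from 0.44 to 0.69. The sign of Zmiz1 turned to -0.06 with a median over probe sets, -0.27 with 1 tumour per title number and -0.11 with Y-linked genes as a covariate, and its difference was 0.00 with the marker covariate. Stat5b turned to -0.02 with array weights, and H2-Aa, Myc and Kit to 0.03, -0.02 and 0.42 with the marker covariate. The Myc target list turned upward with 1 tumour per title number (adjusted p = 0.369), array weights (0.805) and Y-linked genes (0.943), as did thymic epithelium with Y-linked genes (0.887). The Myc target list passed in its original direction with the marker covariate (8.23e-06). With the marker covariate the direction turned for the early progenitor (0.593), mature T-cell (0.216), proliferation (0.593), JAK-STAT (0.531), interferon (0.564), B-cell (0.593), dendritic cell (0.994) and stromal (0.229) lists. Apart from fewer genes tested, the cause was not tested. Leaving out 1 tumour gave 1628 (without Vav-SB replicate 5) to 2518 genes, 10 (without CD4-SB replicate 3) to 15 lists, a similarity of 0.45 to 0.57 and 1143 to 1637 genes whose probe sets differ. It turned Zmiz1 in 5 cases (-0.08 to -0.04, all values -0.08 to 0.29), the Myc target list in 4 (adjusted p = 0.663 to 0.799, all values 0.42 to 0.966) and thymic epithelium in 1 (0.932). Of 83 named genes past the threshold, 25 passed in each of 11 alternatives and without each tumour, as did 4 others in the 10 they were run in, and 66 passed without each tumour. No paired analysis was possible because the labels give no replicate numbers shared between the models, and numbers were given in accession order. With the title number as a random block 2769 genes passed, at a consensus correlation of -0.16. Only CD4-SB tumours share a number, and a negative correlation makes their mean look more precise. That larger count therefore does not show that the calls withstand a shared origin. Signal near background limits dim genes, whose folds are understated.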

Other observations

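The comparison of distances between tumours was written down before its result, and the spread per probe set was chosen after seeing the data.

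Several genes took very different levels among tumours of 1 model, and all of those given here were chosen after their values were seen. Il23r, the interleukin-23 receptor, was at 10.60, 10.60, 11.50 and 11.07 in CD4-SB replicates 1, 2, 5 and 6, and at 6.57, 5.69 and 5.4 in replicates 3, 4 and 7. The same 4 tumours had high Blk, a kinase of B and gamma-delta T cells (10.58, 9.64, 10.55 and 10.48, against 7.14, 6.62 and 6.78), and Clnk (10.28, 10.10, 10.73 and 10.27, against 6.52, 6.19 and 5.94). Replicates 1 and 2 share a title number and replicates 5, 6 and 7 another, so these 4 tumours may not be independent. Il17a was at 11.13 in replicate 1 and 8.25 in replicate 6. The cytotoxic cell genes Ccl5 and Nkg7 were at 11.94 and 12.10 in CD4-SB replicate 3 and at 11.43 and 11.36 in replicate 6.

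Among insertion targets, Erg was at 9.85, 10.18 and 9.73 in Vav-SB replicates 4, 6 and 7, Zmiz1 at 9.89 and 10.41 in CD4-SB replicates 3 and 4, and Akt1 at 9.99 in Vav-SB replicate 2. The proliferation gene Mki67 was lowest, at 9.90, in CD4-SB replicate 3. The Y-linked gene Eif2s3y was at 9.96 in CD4-SB replicate 3 and at 9.95, 10.11 and 9.98 in Vav-SB replicates 4, 5 and 6, and at or below 4.22 in the other tumours. Of 13469 probe sets without a gene name, 963 (7.15%) passed, 643 higher in Vav-SB and 320 higher in CD4-SB.

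Chance is argued against for the count of genes, where 1 of 100 splits of the tumours into 7 and 7, the real one, gave as many, 2284 against at most 240 in the others. So few splits resolve no finer than 1 in 100, and they do not keep tumours with a shared title number together. Chance cannot be excluded for the count of lists at the preset correlation, where 5 of 100 splits gave as many, with 14 lists in the real split and up to 16 in another. With an estimated correlation the real split gave 2 lists and the others at most 1. For genes whose probe sets differ, 1 of 100 splits gave as many, 1508 against at most 1280, and with a spread per probe set 1026 against at most 166. The split with 1280 had 5 Vav-SB tumours on 1 side and 0 genes past the threshold at the gene level.

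The larger distance between CD4-SB tumours could come from different amounts of other cell types. After each gene was regressed on the marker level, the distances were 0.39 in CD4-SB and 0.31 in Vav-SB. The difference shrank from -0.13 to -0.08 and stayed past the threshold (exact permutation p = 0.00117, two-sided), so regression on this mean level did not remove it. That p also shuffled finished distances and is a rough guide only. A single mean cannot remove cell types that vary separately. In CD4-SB the myeloid list was highest in replicate 1 (9.63) and the B-cell list in replicate 5 (8.01). Cytotoxic genes, which are not among the markers, were at 8.72 and 8.74 in replicates 3 and 6. Different amounts of other cell types therefore cannot be excluded. A more varied set of tumours in the CD4-SB model is a hypothesis that was not tested further.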
